A study of Mus musculus with 6 samples.

How the data were processed

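Total RNA from FACS-sorted F4/80-positive cells of dissociated mouse stomach corpus was amplified with a NuGEN Ovation kit, fragmented, made into libraries and sequenced as single-end reads on an Illumina HiSeq instrument, per the labels' protocols. Amplification and the dispase digestion before sorting can each shift transcript levels, and no library preparation date or batch is given in the sources used here. FastQC, TopHat 1.4, SAMtools and the mm9 genome build are named in the submitters' processing notes, without roles. The quantification tool and gene annotation are not given in the sources used here.

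The deposited table holds 1 column per library for 23049 genes. Its header names the values only as normalized, and the unit, RPKM, was recognised here from the values: the deposited value multiplied by gene length falls on whole multiples of a step that differs between libraries, as whole reads scaled by length and depth do. The step gave depths of 4300000 to 20900000 reads per library. It was estimated from genes with a product under 15000 and a length under 4000 nucleotides, and whole reads were not recovered for all genes, so no count-based test was run. The lowest value is exactly 1 in every library. It is a floor, and 7732 genes lie on it in all 6 libraries, so that a listed 1 says only that a gene was at or below it. At 1 RPKM a gene of 1 kilobase holds between 4.3 and 20.9 reads, depending on the library, so the floor hides fewer reads in the shallow libraries than in the deep ones. There were 0 columns of per-sample values left unused.

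The gene coordinates in the table were compared with the GENCODE M21 annotation of GRCm38. Of 22268 genes with an identifier in that annotation, 99.8% overlap the gene of the same identifier and 79.4% share an end with it within 1 bp, so coordinates are given as GRCm38 positions although the processing notes name mm9. Exonic length is the union of a gene's annotated exons in that release, and GC content that of its longest transcript.

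Groups were taken from the sample titles. The numbers in the titles are sample identifiers that no samples of different groups share, so no block was fitted and replicates were numbered within each group. L635 was compared with DMP-777 on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend, two-sided, Benjamini-Hochberg adjustment at 0.05). With the pseudocount of 1 and the floor, fold changes of low genes are understated. The rule fixed before the data were examined kept genes at 1 or more in at least 3 libraries. Since the floor itself is 1, that wording would keep all genes, and the filter was applied as above 1 in at least 3 libraries, which left 12102 genes tested and 10947 not tested. The literal reading was run as an alternative. Among rows that share a symbol, the row with the highest mean stands for the gene.

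The comparison, its tests, most alternatives and 32 gene lists were fixed before the data were examined. The lists were 13 of macrophage programs and cell processes and 19 of cell type markers, with 519 entries, of which 512 were found in the table. They were tested with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with the fry rotation test, each adjusted over the 32 lists. With an estimated correlation, with fry and with fry's mixed test, 0 lists passed. The genes named in the text follow a fixed rule: genes past the threshold whose groups do not overlap, with the smallest p-values up to 5 in each direction where fewer pass. These 5 were also taken from genes with separated groups and a mean log2 level at or above the median of the tested genes, and predicted or clone-named genes were left out, so that genes below that level can have smaller p-values. The rule adds up to 3 members of each list with the smallest p, and Emr1, Il33, Il1rl1, Il13, Arg1, Retnla, Chi3l3, Mrc1, Cd163, Nos2, Il1b and Tnf whatever their result. Genes outside this rule are said to have been chosen after their values were seen. One gene that the rule names is not reported here. Members of families with close paralogs are uncertain where reads can be shared.

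Both steps were tested on simulated data drawn from the real means and spread, with 200 of 12102 genes changed in each of 10 runs and genes drawn independently of each other, unlike real ones. A list of 20 genes shifted by 0.5 on the log2 scale was found by camera in 10 of 10 runs. It was tested alone at an unadjusted p below 0.05, and the rate of false list calls was not simulated. Library quality was compared with exact two-sided permutation tests. Alternatives covered the pseudocount, the filter, quantile normalization, median centring, array weights, the trend and each library left out. Added after seeing the data were the literal filter, removal of a loess trend on exonic length and GC content from each library, the mean level of the general epithelial list as a covariate, and the fit without DMP-777 replicate 1 and L635 replicate 3, the libraries with the lowest mean correlation. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.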

Results

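Macrophages sorted as F4/80-positive cells from the corpus of the mouse stomach were profiled by RNA sequencing after treatment of the animals with DMP-777 or L635. Both compounds cause the loss of acid-secreting parietal cells. L635 is known as an analog of DMP-777 without its inhibition of neutrophil elastase. Per the series' design text, DMP-777 was used to induce spasmolytic polypeptide-expressing metaplasia (SPEM) and L635 to induce SPEM with intestinal features. Doses and treatment times are not given in the sources used here. Each treatment had 3 libraries, named replicate 1 to 3 within their group, and no untreated animals were analysed here. Nothing in the labels says how many animals stand behind each library, so the p-values measure the spread between these samples, which may be partly technical.

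Expression values for 23049 genes were taken as RPKM (reads scaled by gene length and by the depth of the library), a unit recognised from the values. The lowest value was 1 in every library. The depth estimated from the steps between low values was 6900000, 5700000 and 10500000 reads in DMP-777 replicates 1, 2 and 3, and 8700000, 4300000 and 20900000 in L635 replicates 1, 2 and 3. Between 11459 and 12955 genes per library lay above the floor. The mean was 12087 ± 776 genes in DMP-777 and 11926 ± 381 in L635 (SD, n = 3 each, exact two-sided permutation p = 0.9, the smallest possible being 0.1). Pearson correlations of log2(RPKM + 1) across genes were 0.84 to 0.889 within a group and 0.788 to 0.928 between groups, so the ranges overlapped. The closest pair was L635 replicate 1 with DMP-777 replicate 3, at 0.928. The 50 most abundant genes held 10.9 ± 1.57% of the summed RPKM in DMP-777 and 8.53 ± 1.8% in L635 (exact two-sided permutation p = 0.2).

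The comparison of L635 with DMP-777 asks how sorted corpus cells differ between the treatments. The type of metaplasia cannot be told apart from other differences between the compounds, or from dose and treatment time. Transcripts of surface mucous cells, the mucus-secreting cells that line the gastric pits, were lower in the L635 samples by the list test, though not with an estimated correlation between genes (limma camera adjusted p = 0.971 with an estimated correlation) or after quantile normalization (adjusted p = 0.295). All 10 measured markers had a negative log2 fold change, with a median of -0.71, led by the trefoil peptide gene Tff1 at 3475 ± 1544 RPKM in DMP-777 and 863 ± 75.7 in L635 (SD, n = 3 each). The groups were not apart, since the mean log2 level of the list was 7.88 in both DMP-777 replicate 3 and L635 replicate 2. Without DMP-777 replicate 1 the median was -0.49. Random lists matched on exonic length and level had a median of -0.51, and the median of the markers was -0.55 with the trend on length and GC content removed. Nuclear genes of the respiratory chain were also lower in L635 by the list test, 22 of 23 with a median of -0.66, again not with an estimated correlation (limma camera adjusted p = 0.971 with an estimated correlation) or after quantile normalization (adjusted p = 0.182). With the trend on exonic length and GC content removed, the median was -0.42. Their level followed that of parietal cell genes across libraries (Pearson r = 0.95, exact permutation p = 0.011), a relation chosen after seeing the data. The permutation crossed the treatments, so its p also holds the difference between them that both lists share. With group means removed, r was 0.94. Of the parietal cell genes, 10 of 11 were lower, with a median of -0.71. The macrophage marker genes were divided, 8 higher and 9 lower with a median of -0.03. For the alternative activation gene Arg1 and for Il33, the spread within L635 was larger than the difference between the treatments: Arg1 was at 42.8 ± 29.3 RPKM in DMP-777 and 49.8 ± 43.0 in L635, and Il33 was at 16.1 ± 9.47 and 57.1 ± 65.1. No single gene passed the test. Splits of the libraries that mix the treatments called 4 to 17 lists at the preset correlation, against 2 for the real grouping.

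Of 12102 genes tested with limma, 0 passed a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p was 0.308. At an unadjusted p below 0.05 there were 1223 genes, where chance gives about 605 on average. Among splits of the libraries that mix the treatments, 1 gave 1465 such genes and the others 255 to 945. Of the 1223 genes, 457 were higher and 766 lower in L635, so that 37.4% were higher, or 26.5% after centring each library on its median and 47.1% after quantile normalization. The 3 libraries of L635 lay entirely above those of DMP-777 for 877 genes and entirely below for 1059, together 16% of the tested genes, where chance gives 10%. The median 95% confidence interval reached 0.93 to either side of a log2 fold change. In simulated data with the same number of libraries and this spread, with the changed genes drawn from those above the median level, 1.7% of genes changed by 1 on the log2 scale were recovered, 86.6% of those changed by 2 and 99.4% of those changed by 3.

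Among genes at or above the median expression level with separated groups, those with the smallest p-values did not pass. On the lower side they were Mrpl22, a mitochondrial ribosomal protein (chromosome 11, 58171661 to 58179565), and Ndufaf3, an assembly factor of respiratory complex I (chromosome 9, 108565866 to 108567342). Mrpl22 was at 45.6 ± 11.1 RPKM in DMP-777 and 12.7 ± 1.88 in L635, a log2 fold change of -1.75 ± 0.31 (SE, limma adjusted p = 0.308). Ndufaf3 was at 51.0 ± 12.3 and 13.6 ± 5.01, a log2 fold change of -1.87 ± 0.34 (limma adjusted p = 0.308). Sycn, a protein of zymogen granules, had -2.59, the spliceosome core protein Snrpd3 -1.60, and Sptssa, a small subunit of serine palmitoyltransferase, -1.46 (limma adjusted p = 0.406 each). On the higher side, Ptprc, which encodes the leukocyte phosphatase CD45 (chromosome 1, 138062861 to 138175305), was at 21.3 ± 10.6 RPKM in DMP-777 and 64.8 ± 24.6 in L635, a log2 fold change of 1.59 ± 0.38. The nuclear proteins Pnn and Dek had 1.98 and 1.93, the chromatin regulator Ankrd11 1.64, and the interferon-inducible Mndal 1.65, all at a limma adjusted p of 0.406 like Ptprc. In each of these 10 genes the 3 libraries of 1 treatment lay apart from those of the other.

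Genes raised by IL-4 or IL-13 in macrophages, the alternative or M2 program, showed no common direction. Of 23 measured members, 14 were higher and 9 lower in L635, with a median log2 fold change of 0.15 (limma camera adjusted p = 0.701), or an adjusted p of 0.0401 without L635 replicate 3. As fixed, the M2 list shares Alox15 with the eosinophil list, Cd209a with the dendritic cell list and Cdh1 with the general epithelial list. Its result therefore does not read macrophages alone. The resistin-like Retnla was the most abundant of the named M2 markers at 319 ± 97.2 RPKM in DMP-777 and 270 ± 187 in L635. Its log2 fold change was -0.49, with a 95% interval from -1.65 to 0.66, and it ranged from -1.03 without L635 replicate 2 to 0.18 without L635 replicate 3. The interval of Arg1, the arginase of alternatively activated macrophages, ran from -1.25 to 1.58, and that of the chitinase-like Chi3l3 from -0.86 to 0.54; reads of Chi3l3 may be shared with its close paralogs. The scavenger receptors Mrc1 and Cd163 were at 32.8 ± 9.87 and 6.93 ± 1.35 RPKM in DMP-777 and at 54.1 ± 39.9 and 12.8 ± 7.83 in L635, where replicate 2 alone held 98.8 and 21.8. The chemokine Ccl22 had the smallest p of the list, with a log2 fold change of 1.22 (limma adjusted p = 0.496), and Klf4 had 0.46.

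Genes raised by LPS or interferon gamma, the classical or M1 program, were higher for 10 of 17 measured members, with a median of 0.10 (limma camera adjusted p = 0.447). The cytokine gene Tnf was at 6.20 ± 3.47 RPKM in DMP-777 and 16.5 ± 6.86 in L635, a log2 fold change of 1.31 ± 0.48 (limma adjusted p = 0.43). The cytokine-signalling inhibitor Socs3 was at 5.20 ± 0.511 and 15.7 ± 5.55, a log2 fold change of 1.38, and the transcription factor Irf1 had 1.07 (limma adjusted p = 0.409 and 0.453). Il1b was at 99.8 ± 51.8 and 83.1 ± 11.8 RPKM, with a 95% interval of the log2 fold change from -0.99 to 0.81. Nos2, the inducible nitric oxide synthase, lay at the floor of 1 in every library except DMP-777 replicate 1, at 1.5, and was not tested. Adjusted over the list alone, 0 members of either polarization list passed.

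Il33 encodes the alarmin of the IL-1 family named in the title of the series. It stood at 25.9, 7.0 and 15.2 RPKM in DMP-777 replicates 1, 2 and 3 and at 1.4, 128.8 and 41.2 in L635 replicates 1, 2 and 3. The log2 fold change of Il33 was 0.64 ± 1.05 with a 95% interval from -1.62 to 2.91 (limma adjusted p = 0.856). It was -0.58 without L635 replicate 2 and 2.28 without L635 replicate 1. Il1rl1, the receptor of IL-33, was at 2.27 ± 0.659 RPKM in DMP-777 and 7.95 ± 6.23 in L635, with 9.8 and 13 in L635 replicates 1 and 2 and the floor in replicate 3. Il13 was at 5.0 RPKM in L635 replicate 1 and at most 1.3 in any other library, and Il13ra1 had a log2 fold change of -0.20. Of the 13 measured members of the list of IL-33, type 2 cytokines and their receptors, 9 were higher and 4 lower, with a median of 0.03 (limma camera adjusted p = 0.766). Another 7 members, too low in most libraries, were not tested.

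**Figure D1:**
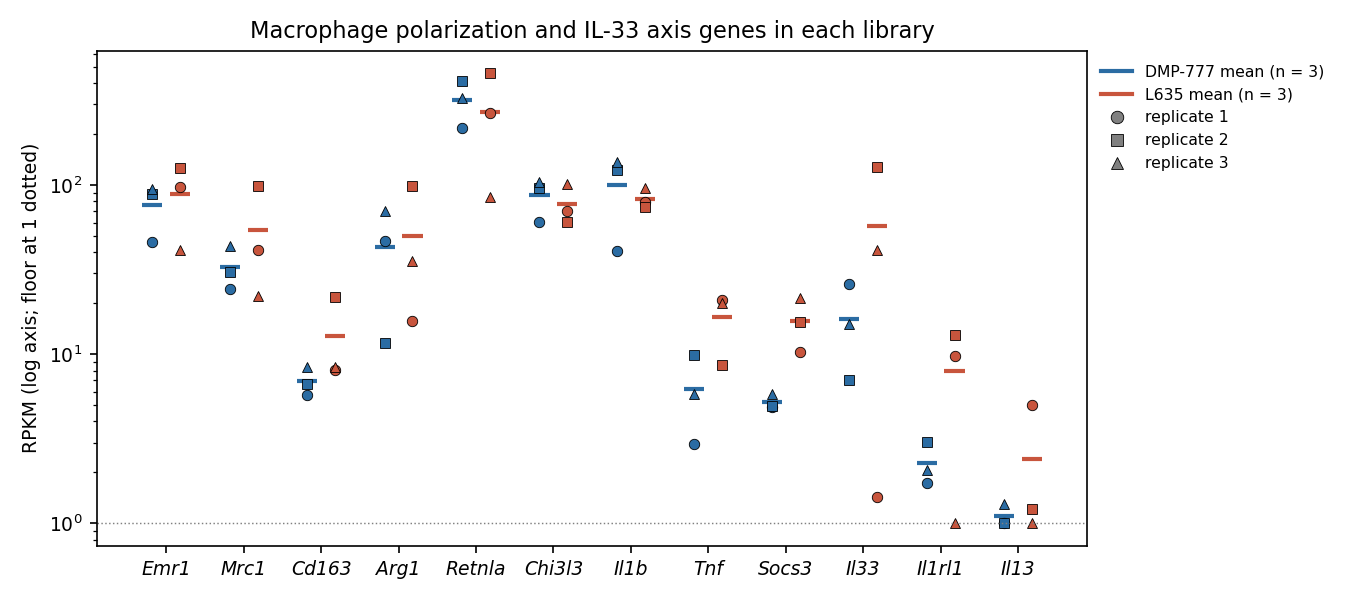
RPKM on a log axis for polarization and IL-33 axis genes in the 3 libraries of each treatment (marker shape gives the replicate, bars the arithmetic group means, the dotted line the floor at 1). Socs3 separates the treatments, at 5.20 ± 0.511 and 15.7 ± 5.55 RPKM, whereas Arg1, Retnla and Il33 spread more widely within L635 than between the groups.

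The respiratory chain list held 23 tested genes, 22 of them lower in L635, and it passed the list test (limma camera adjusted p = 8.8e-06), although not with an estimated correlation between genes (adjusted p = 0.971 with an estimated correlation). Quantile normalization also ended this call, at an adjusted p of 0.182. The median was -0.41 without DMP-777 replicate 2, -0.45 without L635 replicate 3 and -0.40 with the general epithelial level as a covariate, and random lists matched on exonic length and level had a median of -0.47. Further, the level of the list in DMP-777 replicate 3, 6.31, lay below that in L635 replicate 1, 6.36. Uqcrfs1, the Rieske iron-sulfur protein of complex III, was at 156 ± 72.3 RPKM in DMP-777 and 71.4 ± 20.2 in L635, a log2 fold change of -1.06 ± 0.38. The complex I genes Ndufs3 and Ndufa1 had -0.88 and -0.95, each with an adjusted p of 0.422 from limma. Of the 23 genes, 8 were lower at an unadjusted p below 0.05, and 0 passed adjusted over the list alone or over all genes. The level of this list followed that of the parietal cell list across the 6 libraries (Pearson r = 0.95, exact permutation p = 0.011, Spearman rho = 0.94, exact permutation p = 0.017, and r = 0.76 without the 2 libraries farthest from the parietal median; chosen after seeing the data, and the only such relation computed). Both lists were lower in L635, and these permutations crossed the treatments, so their p-values also hold that shared difference. Of the glycolysis and hypoxia genes, 16 of 22 were lower with a median of -0.31 (limma camera adjusted p = 0.447), and the direction of the test turned under quantile normalization. The mitophagy receptor Bnip3 had -0.86.

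Type I interferon targets were higher in L635 for 19 of 24 members, with a median of 0.45, and did not pass (limma camera adjusted p = 0.0867). The call depended on the libraries used: the adjusted p was 0.00334 without DMP-777 replicate 1, 0.00436 without L635 replicate 1 and 0.014 without L635 replicate 2, but 0.848 without L635 replicate 3 and 0.777 without DMP-777 replicate 2 (adjusted p = 0.971 with an estimated correlation for all 6 libraries). The mean level of the list was 4.75 in L635 replicate 3, against 3.51 and 3.46 in L635 replicates 1 and 2 and at most 3.89 in DMP-777. The RNA sensor Ddx58 was at 4.84 ± 1.67 RPKM in DMP-777 and 12.1 ± 4.78 in L635 and the antiviral Mx2 at 1.95 ± 0.328 and 6.48 ± 4.94, log2 fold changes of 1.14 and 1.16. The ubiquitin-like Isg15 had the opposite sign, with 50.03 ± 12.5 and 17.2 ± 10.7 RPKM and a log2 fold change of -1.69 (limma adjusted p = 0.406). Genes of MHC class II presentation were lower for 9 of 11, with a median of -0.36 (limma camera adjusted p = 0.376, or 0.00445 without DMP-777 replicate 1), and the direction of the test turned under quantile normalization. The transactivator Ciita, at 0.69, was an exception.

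Of the lipid handling and lysosome genes, 15 of 22 were lower, with a median of -0.26 (limma camera adjusted p = 0.359), and the direction of the test turned under quantile normalization. The tetraspanin Cd63 was at 262 ± 51.0 RPKM in DMP-777 and 136 ± 57.0 in L635, and the fatty acid receptor Cd36 had a log2 fold change of -0.86. Efferocytosis and complement genes were lower for 15 of 24, with a median of -0.32 (adjusted p = 0.376 by limma camera), including the complement component C1qa at -1.39 and the folate receptor Folr2 at -1.21. Chemokines and their receptors were lower for 10 of 18, with a median of -0.37 (adjusted p = 0.6 by limma camera). The monocyte attractants Ccl12 and Ccl2 had -1.86 and -0.91. Matrix remodelling genes were lower for 13 of 22, with a median of -0.08 (adjusted p = 0.701 by limma camera, or 0.0259 without DMP-777 replicate 1), with the protease inhibitor Timp1 at -1.37 and the platelet factor Pf4 at -1.13. Proliferation genes were divided, 15 higher and 11 lower (adjusted p = 0.801 by limma camera), with Mki67 and Top2a at 1.57 and 1.09 and the ubiquitin-conjugating enzyme Ube2c at -0.87. Immediate early and heat shock genes were higher for 12 of 20, with a median of 0.16 (adjusted p = 0.868 by limma camera), although Egr1 was at 85.6 ± 18.2 RPKM in DMP-777 and 43.9 ± 17.8 in L635.

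Transcripts of gastric epithelium were abundant in these sorted samples. Tff1 was the most abundant gene of all 3 DMP-777 libraries, and the surface mucous gene Gkn2 of L635 replicate 3, while the myeloid lysozyme Lyz2 led in L635 replicate 1 and the predicted gene Gm20594 in L635 replicate 2 (Gkn2, Lyz2 and Gm20594 were chosen after their values were seen). In comparison, the F4/80 gene Emr1 stood at 76.3 ± 26.3 RPKM in DMP-777 and 88.7 ± 43.6 in L635. The surface mucous list passed the list test (limma camera adjusted p = 8.65e-05), although not with an estimated correlation between genes (adjusted p = 0.971 with an estimated correlation). The call also ended with quantile normalization, at an adjusted p of 0.295, and without DMP-777 replicate 1 and L635 replicate 3 together, at 0.0715. With 1 library left out, the median ranged from -0.49 without DMP-777 replicate 1 to -0.98 without DMP-777 replicate 3. The level of the list was 9.11, 8.86 and 7.88 in DMP-777 replicates 1, 2 and 3 and 7.74, 7.88 and 7.60 in L635 replicates 1, 2 and 3. With the general epithelial level as a covariate the median was -0.38 (adjusted p = 0.031). Gkn1, a gastrokine of surface cells, was at 1394 ± 605 RPKM in DMP-777 and 515 ± 40.6 in L635, and the surface antigen Psca at 778 ± 337 and 345 ± 95.6, log2 fold changes of -1.32 and -1.10 (limma adjusted p = 0.435 and 0.455). Tff1 (chromosome 17, 31161396 to 31165053) had -1.90 ± 0.60, with an adjusted p of 0.413 from limma, and 0 members passed adjusted over the list alone.

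Parietal cell genes were lower in L635 for 10 of 11, with a median of -0.71, and did not pass (limma camera adjusted p = 0.0518, with a range from 0.000967 to 0.467 when 1 library was left out, past the threshold without DMP-777 replicate 3 at 0.000967, L635 replicate 1 at 0.014 or L635 replicate 2 at 0.0117, and not without the others). With an estimated correlation between genes, the parietal list had a limma camera adjusted p of 0.971. The proton pump gene Atp4a was at 208 ± 106 RPKM in DMP-777 and 127 ± 98.0 in L635, and the potassium channel subunit Kcne2 had a log2 fold change of -1.41. Chief cell genes had a median of -0.26 (limma camera adjusted p = 0.846), with the pepsinogen Pgc at 627 ± 163 and 523 ± 32.7 RPKM, and both the list and Pgc turned direction under quantile normalization. Mucous neck and SPEM genes were divided, 5 higher and 4 lower (adjusted p = 0.868 by limma camera; the median of 0.09 and the direction of the test differ in sign), with Tff2, which encodes spasmolytic polypeptide, at 398 ± 30.1 and 268 ± 76.0 RPKM and Olfm4 at 8.28 ± 6.06 and 1.91 ± 0.832. Intestinal-type epithelial genes were 3 higher and 3 lower among 6 measured, with 7 not tested (adjusted p = 0.868 by limma camera; here too the median of 0.05 and the direction of the test differ in sign). Gpx2 of that list had -1.03. General epithelial genes were lower for 9 of 11, with a median of -0.31 (adjusted p = 0.297 by limma camera, or 0.0292 without DMP-777 replicate 3), and the direction of the test turned under quantile normalization. Krt20 of that list had -1.74.

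Among leukocytes, the macrophage list had an adjusted p of 0.846 by limma camera, with Cd68 at 279 ± 51.2 RPKM in DMP-777 and 189 ± 67.5 in L635. The log2 fold change of Emr1 was 0.14, with a 95% interval from -0.78 to 1.05. The monocyte list had a median of 0.18 (adjusted p = 0.6 by limma camera). The neutrophil list had a median of 0.01 (adjusted p = 0.868 by limma camera), and the dendritic cell list, with 5 of 10 higher, had the same adjusted p, its median and mean differing in sign. Genes of T, NK and innate lymphoid cells were 3 higher and 3 lower (adjusted p = 0.965 by limma camera), and the 4 measured B and plasma cell genes were lower, with a median of -0.36 (adjusted p = 0.447 by limma camera). Fibroblast, smooth muscle, endothelial and erythroid lists had medians of -0.29, -0.36, -0.16 and 0.11, and adjusted p-values of 0.801, 0.728, 0.868 and 0.766 by limma camera. Reads of the hemoglobin genes may be shared between copies.

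**Figure D2:**
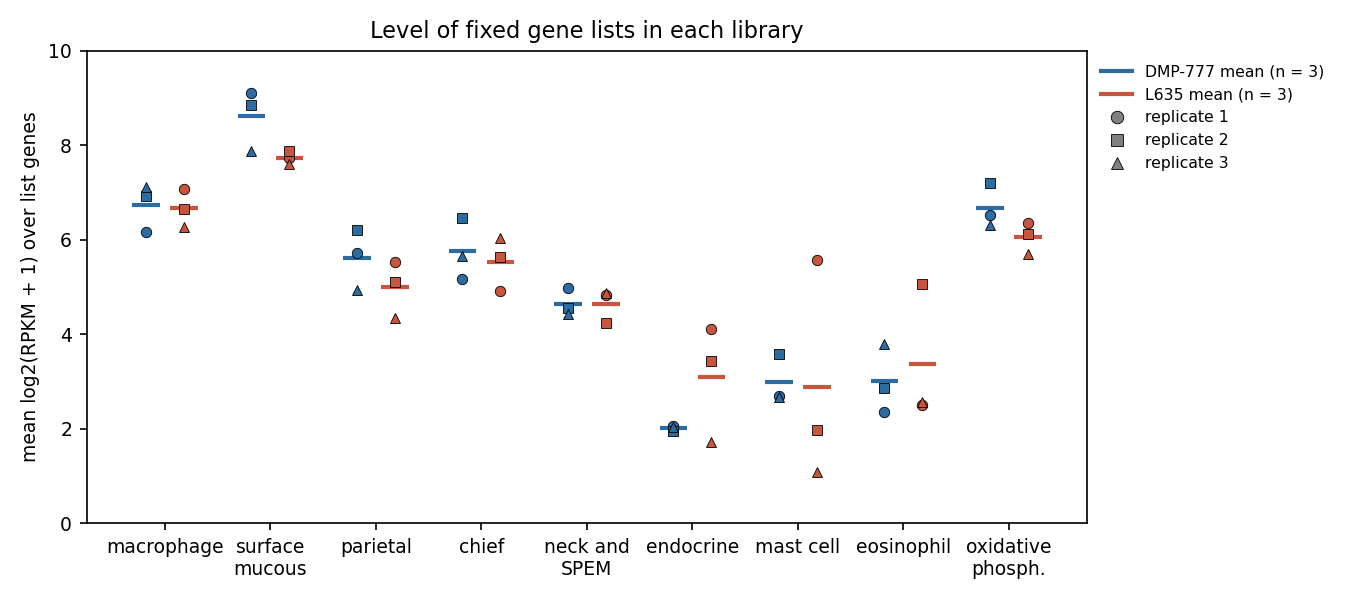
Mean log2(RPKM + 1) over the tested genes of 9 fixed lists in each library (marker shape gives the replicate, bars the group means, n = 3 per treatment; SPEM, spasmolytic polypeptide-expressing metaplasia). The surface mucous level is 8.62 ± 0.65 in DMP-777 and 7.74 ± 0.14 in L635, the macrophage level 6.74 ± 0.50 and 6.67 ± 0.40, and the mast cell and eosinophil levels each stand out in 1 L635 library.

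The fold changes varied with the length of the genes' exons. Across 12002 genes, which are not independent replicates, the log2 fold change and exonic length had a Spearman correlation of 0.372. The shortest decile, with a median of 1223 nucleotides, had a median log2 fold change of -0.45, and the longest decile, with a median of 12345 nucleotides, 0.37. Among the genes named above, Mrpl22, Tff1, Isg15 and Ndufa1, lower in L635, have exonic lengths of 981, 703, 756 and 419 nucleotides, whereas Ptprc, Ankrd11 and Mki67, higher in L635, have 18313, 16580 and 10061. Other named genes did not follow the trend: Tnf, Socs3 and Dek, also higher, have 1639, 2891 and 3185, and Snrpd3, lower, has 3442. With the trend on length and GC content removed from each library, an alternative chosen after seeing the data, 0 genes passed (limma). The median of the respiratory chain list was then -0.42 and that of the surface mucous list -0.55 (limma camera adjusted p = 0.00334 and 0.00425, and adjusted p = 0.906 for both with an estimated correlation).

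**Figure D3:**
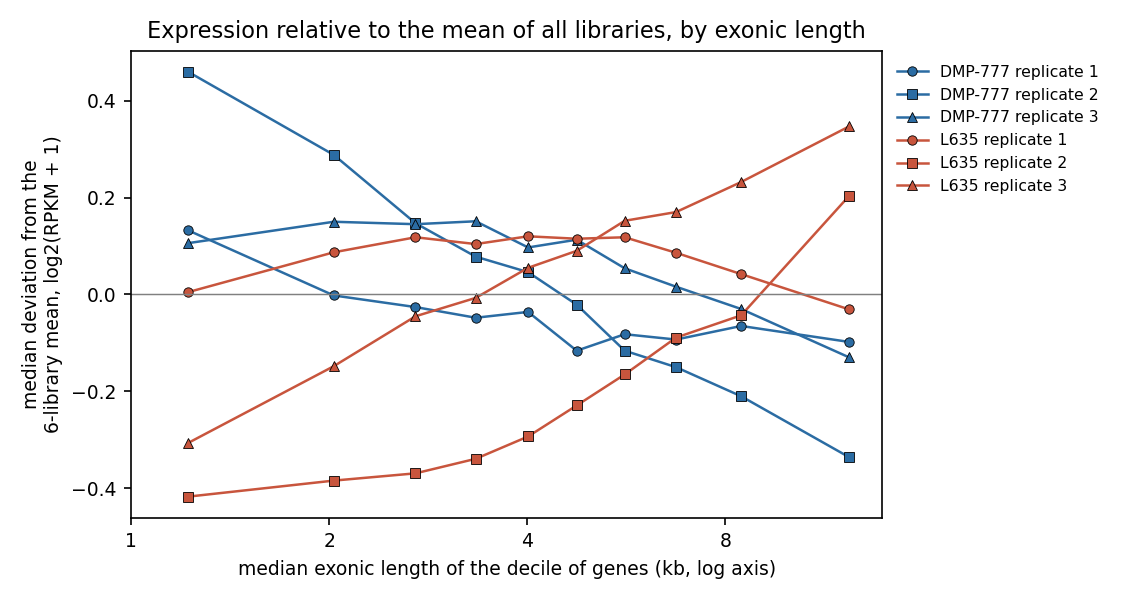
Median deviation of each library from the mean of the 6 libraries, in log2(RPKM + 1), for deciles of the genes ordered by exonic length (log axis, kilobases). L635 replicates 2 and 3 are at -0.42 and -0.31 in the shortest decile and 0.20 and 0.35 in the longest, DMP-777 replicate 2 goes from 0.46 to -0.34, and L635 replicate 1 stays between -0.03 and 0.12.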

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

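The literal filter, the removal of the length and GC trend, the epithelial covariate and the fit without DMP-777 replicate 1 and L635 replicate 3 were chosen after seeing the data. Under every alternative run, 0 genes passed (limma), the smallest adjusted p being 0.0611 without DMP-777 replicate 3. All 2001 alternative values of the 113 genes named by the rule therefore stayed on the same side of the threshold, which says nothing about their stability. The log2 fold changes of Arg1, Il33, Mrc1, Retnla, Il1b, Emr1 and Chi3l3 turned sign in some of these fits. Of 636 alternative values of the lists, 602 stayed on the same side of the threshold. Only 2 of the 32 lists passed in the main fit, so most of these values belong to lists that passed in neither fit. The count therefore says little about the stability of the lists. The number of genes at an unadjusted p below 0.05, 1223, ranged from 622 to 1581 with 1 library left out (622 without DMP-777 replicate 2, 652 without L635 replicate 3 and 808 without L635 replicate 2). It was 369 with the epithelial covariate and 604 without DMP-777 replicate 1 and L635 replicate 3. The share of these genes that were higher, 37.4%, was 47.1% with quantile normalization and 26.5% with median centring. No paired analysis was possible because the groups share no replicate numbers in the labels, and the planned count-based alternative was not run because the table holds no counts.

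The number of gene lists past the threshold, 2, was 0 with quantile normalization, 0 with an estimated correlation and 0 with fry, 4 with array weights, 2 to 5 with 1 library left out, 5 with the length and GC trend removed, 8 with the epithelial covariate and 4 without DMP-777 replicate 1 and L635 replicate 3. The adjusted p of the surface mucous list was 0.295 with quantile normalization, 0.0715 without DMP-777 replicate 1 and L635 replicate 3, 0.971 with an estimated correlation and 0.97 with fry. That of the respiratory chain list was 0.182 with quantile normalization, 0.971 with an estimated correlation and 0.97 with fry. The interferon list passed with array weights (0.00957), with the length and GC trend removed (0.0176) and in 3 of the 6 fits with 1 library left out (range 0.00334 to 0.848). With 1 library left out, the adjusted p ranged from 0.00445 to 0.857 for MHC class II, from 0.0259 to 0.848 for matrix remodelling, from 0.0401 to 0.6 for the M2 list and from 0.000325 to 0.875 for the mast cell list, which turned lower in L635 at 0.000325 without L635 replicate 1 and passed as higher at 0.0316 without L635 replicate 3. With the epithelial covariate, chemokines (0.0278), lipid handling (0.0154), MHC class II (0.00759) and matrix remodelling (0.00746) also passed, lower in L635, as did endocrine (0.00746) and erythroid genes (0.0287), higher in L635, and MHC class II passed without DMP-777 replicate 1 and L635 replicate 3 (0.0194, lower), as did the endocrine (0.000367) and erythroid lists (0.0378, both higher). The parietal list passed with array weights (0.0248) and, like the endocrine list, with the length and GC trend removed (0.043 each). The cause of these shifts was not tested. Depth limits genes near the floor, which hides up to 20.9 reads per kilobase in the deepest library and 4.3 in the shallowest.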

Other observations

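The relation with the parietal list, the gap between epithelial levels, the count of mast cell markers by library, the counts of genes in other splits of the samples and the lists in those splits with an estimated correlation were tested only after the result was seen. Weighing the fit with the length trend removed, with its estimated correlation, beside the matched lists was also decided after these were seen.

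Single L635 libraries stood out for other immune cells; Cpa3, Alox15, Siglec5 and Ccr3 were chosen after their values were seen. Of the 12 mast cell markers measured, 11 were highest in L635 replicate 1, where the carboxypeptidase Cpa3 was at 116 RPKM against 1 to 20.2 in the other libraries, the stem cell factor receptor Kit at 33.7 and the protease Mcpt2 at 391. The list as a whole had an adjusted p of 0.965 by limma camera, its mean of -0.11 and median of 0.16 differing in sign. Eosinophils also carry F4/80, and of their 9 measured markers all but Ear1 and Ear2 were highest in L635 replicate 2, with Alox15 at 162 RPKM, the lectin Siglec5 at 51.0 and Ccr3 at 77.5 (limma camera adjusted p = 0.667 for the list, 6 of 9 higher). Mcpt and Ear genes have close paralogs, so their single values are uncertain. Endocrine cell genes were higher in L635 for all 4 measured members, with 7 not tested and a median of 0.85 (limma camera adjusted p = 0.135, from 0.000199 without L635 replicate 3 to 0.479 without L635 replicate 1, and adjusted p = 0.971 with an estimated correlation). Of the 4, Hdc is also a mast cell marker and was highest in L635 replicate 1. Chga was at 11.5 RPKM in that library and at most 1.12 in any other. The level of the endocrine list in L635 replicate 3, 1.72, lay below that of every DMP-777 library. The ghrelin gene Ghrl was at 65.8 and 84.1 RPKM in L635 replicates 1 and 2, 5.9 in replicate 3 and 8.31 ± 7.30 in DMP-777 (SD, n = 3). Batf, a transcription factor of the AP-1 family, lies below the median level and was chosen after its values were seen; it has a smaller p than the higher genes named by the rule. Batf was at 1.4 ± 0.53 RPKM in DMP-777 and 11.3 ± 2.16 in L635, a log2 fold change of 2.37 ± 0.44 (SE, limma adjusted p = 0.308).

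The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real grouping is included in each of the following counts of splits. For genes past the adjusted threshold, 10 of the 10 splits gave as many as the real 0, the highest other count being 1. Any split reaches a count of 0, so that comparison could not have come out otherwise. For genes at an unadjusted p below 0.05, 2 of 10 gave as many as the real 1223, the highest other count being 1465, from DMP-777 replicate 1 with L635 replicates 2 and 3 against the rest. For gene lists, 10 of 10 gave as many as the real 2, and the highest other count was 17. The splits that mix the treatments called 4 to 17 lists at the preset correlation, and with an estimated correlation every split called 0.

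The lower respiratory chain genes in L635 were weighed against transcript length and against carried-over parietal cells, which are rich in mitochondria and whose list shares no gene with this one. Length stays open: their median of -0.66 lay at percentile 2.05 of 10000 random lists matched on exonic length and level, whose own median was -0.47, but these lists treat genes as independent while the estimated correlation within this list was 0.821, and with the length trend removed the median was -0.42 (limma camera adjusted p = 0.00334, and adjusted p = 0.906 with an estimated correlation). Carried-over parietal cells stay open too: with group means removed, the list level followed the parietal list over the 6 libraries (Pearson r = 0.94). The permutation p of 0.013 for this r is not exact, because centred levels were exchanged between the groups. No conclusion is drawn from that p. The proton pump subunit Atp4b was at 364 ± 167 RPKM in DMP-777 and 234 ± 160 in L635 (chosen after its values were seen). Sorting on F4/80 should remove such cells, although their genes were measured here. Every cell expresses respiratory chain genes, and the share of that RNA supplied by parietal cells was not tested. The medians of the respiratory chain and parietal lists were -0.66 and -0.71, or -0.42 and -0.635 with the length and GC trend removed. A difference between the treatments in the macrophages themselves also stays open, as untested.

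The lower surface mucous genes in L635 may reflect transcript length, less carried-over epithelium of every kind, or a difference in the mucosa itself, which was not tested. Their median lay at percentile 7.41 of random lists matched on length and level, inside the range of such lists, which had a median of -0.51 against -0.71, and with the length trend removed the adjusted p was 0.00425 by limma camera (adjusted p = 0.906 with an estimated correlation), so the length explanation cannot be told apart from the treatment on these values. The gap between the surface mucous level and the mean of the mucous neck and chief cell levels differed by -0.76 on the log2 scale, more than its pooled SD of 0.53, but overlapped between the groups, and with the general epithelial level as a covariate the median was -0.38 and the adjusted p 0.031 by limma camera at the preset correlation, so a general loss of epithelium cannot be told apart either with 3 libraries a group. No marker of the surface mucous list is in another of the lists. Sorting on F4/80 should remove these cells, but their transcripts were among the most abundant in these samples.

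Il1rl1 at 9.8 RPKM and Il13 at 5.0 in L635 replicate 1 may come from mast cells, which are known to express both, since 11 of the 12 mast cell markers were highest in that library. One of them, Hdc, is also in the endocrine list. The explanation does not reach Il1rl1 at 13 RPKM in L635 replicate 2, where the mast cell level of 1.97 was below that of every DMP-777 library. That library had the highest level of the eosinophil list, 5.06, and the cell source of its Il1rl1 was not tested. Sorting on F4/80 should remove mast cells, although their markers were measured here. A treatment effect on Il1rl1 in macrophages was not separated from other cell sources by any test.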
